A study of Mus musculus with 10 samples.

How the data were processed

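RNA was sequenced from keratinocytes of FVB/N mouse skin at postnatal day 4, sorted by flow cytometry into basal and suprabasal cells. There were 10 samples: 3 wild type and 2 bitransgenic samples of basal cells, and 3 wild type and 2 bitransgenic samples of suprabasal cells. The bitransgenic mice model Hutchinson-Gilford progeria (HGPS) and carry progerin, a truncated form of lamin A. Per the labels, strand-specific libraries were made from nanogram amounts of total RNA with an amplifying kit. The titles have 6 stems, and 3 wild type stems and 1 bitransgenic stem occur in both layers.

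The submitters' processing notes name TopHat, Cufflinks and the mm10 mouse genome build, without versions. The authors deposited 1 comparison table per layer, and its header has the form of a Cuffdiff table. Each line of a table is a locus, with 1 level per genotype. The level is the authors' group value, read here as FPKM (fragment counts scaled by transcript length and library size) from the form of the deposited tables and the tools named, since the header gives no unit. The deposited fold changes are log2 ratios, the deposited test statistic is a score, and the deposited p-value and q-value (adjusted p) are the authors' own. How the authors scaled the libraries against each other is not stated, and the tables of the layers were normalized separately. Because each group is represented by 1 pooled value, no spread between replicates could be computed and no depth per sample is known. No paired analysis was possible, because the values of the single animals were not among those analysed here, and leaving out 1 replicate at a time was not possible for the same reason.

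The basal table held 11316 loci, of which 11290 had the status OK, and the suprabasal table held 11490 loci, of which 11464 had the status OK. The remaining 26 loci of each table have the status HIDATA and were left out of every comparison. The deposited log2 fold changes were checked against the levels, and the largest difference was 4.13e-05. Loci that name several gene symbols or none (368 in the basal table and 372 in the suprabasal table) are called merged below. No locus of status OK had a level of 0 in either group.

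All fold changes are given as bitransgenic over wild type. A gene was called when its status was OK and the authors' q was under 0.05. The authors' q could not be recomputed by Benjamini-Hochberg adjustment over the analysed loci, so the counts from that adjustment were computed as an alternative. A standard error (SE) of each log2 fold change was derived as its absolute value divided by the two-sided normal quantile of the authors' p. The p was used because the deposited test statistic did not give the p by the normal distribution: the median ratio of the statistic to the normal quantile was 0.631 in basal and 0.629 in suprabasal cells. The smallest p in the tables is 5e-05, shared by 44 basal and 35 suprabasal loci, and for these the SE is an upper bound.

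The difference between the layers was tested per gene with a two-sided Wald z-test on the suprabasal minus the basal log2 fold change, with Benjamini-Hochberg adjustment over the 10583 loci of status OK in both tables. The test treats the layers as independent, although title stems recur in both layers, and the labels do not say whether a stem is an animal. Overlap of calls was described with two-sided Fisher's exact tests. For each gene list, the number of called members was counted at the authors' q, and again after Benjamini-Hochberg adjustment of the authors' p over the list alone. The median log2 ratio of the list, with a pseudocount of 1 FPKM, was placed among 10000 random lists of the same size drawn from 20 bins of mean level. A list outside the central 95% of random lists (below percentile 2.5 or above 97.5) is described as outside their range. These percentiles describe the tables and are not p-values, since genes in a list are not independent.

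The groups, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The 32 lists covered basal keratinocyte, early differentiation, cornified envelope, epidermal barrier lipid, and wound and stress genes, and Wnt targets and Wnt ligands, receptors and effectors. They also covered the nuclear envelope, polarity and spindle orientation, cell cycle, p53 and senescence, cytokines, interferon response, Notch, Hedgehog, hair follicle, sebaceous gland, cholesterol synthesis, basement membrane, and desmosomes and junctions. Marker lists covered fibroblasts, leukocytes, endothelium, melanocytes, Schwann cells, muscle, erythroid cells, adipocytes and Merkel cells. The remaining lists held immediate early and heat shock genes, ribosomal protein genes and mitochondrially encoded genes. Lists of imprinted, histone and Y-linked genes were written after the data had been seen.

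The named genes were, per layer, the 6 largest rises and the 6 largest falls among called genes with at least 5 FPKM in the higher and at least 0.1 FPKM in the lower group. Merged loci, predicted or RIKEN gene models, microRNAs and small RNAs were excepted from that part. In addition, up to 3 called members per list under the same level rule were named, with merged loci allowed. Krt5, Krt14, Krt1, Krt10, Itga6, Lmna, Emd, Tmpo, Sun1, Sun2, Lmnb1, Ctnnb1, Lef1 and Axin2 were always named. For the layer difference, the 8 genes of smallest adjusted p were named. Where a symbol had several loci, the locus of highest mean level was used. In suprabasal cells only 4 rises met the rule. Not every gene that the rule takes is used here.

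Gene coordinates and short RNA genes were taken from GENCODE mouse release 21 on mm10, with positions counted from 1. The tests were also tried on simulated data. In 10579 genes, the layer-difference test recovered 23% of simulated differences of 2 and 64% of those of 4 log2 units, and 4.40% of its calls were false. That simulation drew the layers independently and took the derived SE as true, so these shares need not hold for the data. The list percentile placed 7% of unshifted lists of 20 genes outside the central range in basal cells (11290 genes) and 3% in suprabasal cells (11464 genes). For lists shifted by -0.5 the shares were 98% and 100%. Alternatives varied the q threshold, minimum fold change, minimum level, pseudocount, merged loci, adjustment, centring, matching of the random lists and source of the SE. Work was done with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.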

Results

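Gene expression was measured by RNA sequencing in sorted skin keratinocytes of 4-day-old mice, with 3 wild type and 2 bitransgenic samples in the basal layer and the same numbers in the suprabasal layer. Basal keratinocytes attach to the basement membrane and divide, and suprabasal cells have left it and differentiate. The levels are the authors' values, 1 per group, read as FPKM from the form of the deposited tables, so no level carries an error of its own, and the depth of the samples is unknown. The ± beside a log2 fold change is the SE implied by the authors' p-value, which is an upper bound where that p is the smallest in the table. The title of the series names the symmetry of cell division, Wnt signalling and nuclear envelope proteins, and gene lists for these were read first.

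The sort was checked on the wild type groups, with the reservation that the tables of the layers were normalized separately. Of the basal keratinocyte genes, 22 of 24 had the higher level in basal cells, and so did 40 of 40 cell cycle genes. Of the early differentiation genes 20 of 24, of the cornified envelope genes 23 of 25 and of the barrier lipid genes 22 of 24 had the higher level in suprabasal cells. Krt10, a keratin of differentiating cells, stood at 2319 FPKM in basal and 6574 FPKM in suprabasal wild type cells. In bitransgenic cells some of these markers separated the layers less: the suprabasal level over the basal level was 1.47 for Krt10 and 0.927 for Krt1, against 2.83 and 1.98 in wild type, while Lor had 9.28 against 1.60. Itga6, an integrin of basal cells, stood at 241 and 106 FPKM. The melanocyte gene Dct stood at 4.00 FPKM in basal and 1122 FPKM in suprabasal wild type cells, and the mesenchymal and melanocyte gene Vim at 2.32 and 316 FPKM.

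In basal cells, the question was how progerin changes the cells that divide. Some genes of the Wnt pathway fell. Wnt16 went from 33.3 FPKM in wild type to 6.18 in bitransgenic cells and Wnt3a from 13.0 to 3.87. Lef1, a transcription factor of Wnt signalling, went from 12.6 to 3.02 FPKM. The stem cell keratin Krt15 fell from 1602 to 308 FPKM and the growth factor gene Igf2 from 329 to 5.03. The antimicrobial S100a9 rose from 50.7 to 250.4 FPKM and its partner S100a8 from 178 to 704. In all, 186 of 11290 genes were called at the authors' q, 29 higher and 157 lower in bitransgenic cells.

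Among the Wnt ligands, receptors and effectors in basal cells, 52 were measured, 4 fell and none rose. Adjusted over the list alone, 8 fell and none rose. Wnt16 changed by -2.43 ± 0.60 on the log2 scale, the receptor gene Ror1 by -2.29 ± 0.71 (7.36 to 1.51 FPKM) and Wnt3a by -1.75 ± 0.45. The fourth was Wnt6, which fell from 15.8 to 5.90 FPKM. The list median was -0.43, below all 10000 random lists, and 46 of the 52 members lay below 0. The list also names antagonists of the pathway, such as Sfrp1 and Dkk2, so its median gives no direction of Wnt signalling. Of 17 Wnt targets, Lef1 alone fell (-2.07 ± 0.51, on chromosome 3 from 131110471 to 131224356), as it did adjusted over the list alone. The median of the targets was -0.37, at percentile 1.89 of the random lists. Axin2, a feedback target of the pathway, had 17.0 FPKM in wild type and 13.7 in bitransgenic cells (-0.30 ± 0.33), and Ctnnb1, which encodes beta-catenin, 159 and 150.3 FPKM (-0.08 ± 0.38). Both missed the threshold.

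Few nuclear envelope transcripts passed the test in basal cells. Of 37 genes, 1 fell at the authors' q, Tmem43, which encodes an inner nuclear membrane protein (85.0 to 28.3 FPKM, -1.59 ± 0.50). When adjusted over the list alone, none passed. The nuclear envelope list had a median of -0.07, at percentile 45.8. Lmna, the gene of lamin A, had 564 and 536 FPKM (-0.07 ± 0.37, or 0.04 after centring). Sun1, which couples the nucleus to the cytoskeleton, had 25.7 and 18.5 FPKM (-0.48 ± 0.26), and Sun2 15.4 and 15.4 FPKM (0.11 after centring). Emd had 50.9 and 65.3 FPKM, Tmpo 61.7 and 61.7 FPKM, and Lmnb1 51.0 and 54.9 FPKM, and these too missed the threshold. None of the 34 genes for polarity and spindle orientation passed, by either adjustment, and their median was -0.03, at percentile 68.8. Of 40 cell cycle genes, Top2a, a topoisomerase of dividing cells, rose from 83.2 to 196 FPKM (1.23 ± 0.30), at either adjustment (over all genes or adjusted over the list alone). The median of the list was 0.07, at percentile 96.4.

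Genes typical of basal cells were lower as a list. Of 24 basal keratinocyte genes, 3 fell and none rose, and 4 fell adjusted over the list alone. Besides Krt15 (-2.38 ± 0.71, on chromosome 11 from 100131758 to 100135928), these were the IGF-binding protein Igfbp3 (30.8 to 3.30 FPKM) and the metallothionein Mt2 (1099 to 449 FPKM). The whole list had a median of -0.40, at percentile 0.06. Itga6 had 241 and 219.5 FPKM, the merged locus of Krt14 and Krt16 4375 and 3926 FPKM, and the merged locus that holds Krt5 and Krt8 11677 and 6923 FPKM, and none of these passed. Of 23 basement membrane genes, 3 fell and 4 fell adjusted over the list alone, none rising. The 3 were the collagen genes Col4a6 (13.9 to 4.16 FPKM) and Col4a5 (12.9 to 6.13 FPKM) and the protease gene Adamts1 (51.1 to 20.5 FPKM). The list median was -0.54, at percentile 0.02 (-0.31, at percentile 0.44, with a pseudocount of 5 FPKM).

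Genes of the skin barrier had opposite medians in basal cells. Of 24 barrier lipid genes, 3 rose and none fell, and 5 rose adjusted over the list alone. The hydroxylase Fa2h went from 3.57 to 10.6 FPKM, the lipid transporter Abca12 from 10.8 to 25.2 and the elongase Elovl4 from 34.7 to 69.1, and the list median of 0.40 lay above all random lists. Of 25 cornified envelope genes, the protease inhibitor Cst6 rose from 3.55 to 11.5 FPKM and the envelope protein Lor fell from 17.2 to 3.18 FPKM. Counted as adjusted over the list alone, 4 rose and 3 fell, and the list median was -0.78, below all random lists. Genes of low level carry part of that value: it was -0.43, at percentile 1.5, with a minimum of 5 FPKM, and -0.48 with a pseudocount of 5 FPKM. The list includes the Lce1 family of related genes, so its members are not independent. Lce1b had 13.1 and 0.840 FPKM (-3.96 ± 3.37), while Ivl had 4.14 and 9.29 FPKM and Tgm1 4.54 and 10.7 FPKM. None of these was called. Of the 25 members, 7 lay above 0 and 18 below, so the median does not give the direction of every member. Of 24 early differentiation genes, the desmosomal cadherin Dsc1 rose (13.7 to 38.1 FPKM), at either adjustment, with a list median of -0.06 at percentile 44.4. Krt1 had 1725 and 1749.7 FPKM and Krt10 2319 and 1601 FPKM, and neither passed. Of 29 desmosome and junction genes, Dsc1 and the connexin Gjb2 (8.49 to 23.2 FPKM) rose, at either adjustment, with a list median of 0.15 at percentile 98.8.

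Wound and stress genes of keratinocytes were the list with the highest median in basal cells among those with at least 5 measured members. Of 27 measured, 4 rose and none fell, at either adjustment: S100a9 (2.30 ± 0.57), S100a8 (1.99 ± 0.49), Gjb2 and the merged locus of Sprr1b and Gm9774 (45.8 to 162 FPKM). The 27 genes had a median of 0.81, above all random lists (1.28 without merged loci). Of 31 cytokine and receptor genes, the chemokine Ccl20 rose from 56.9 to 180 FPKM and the cytokine Tnf from 6.71 to 20.7 FPKM. Adjusted over the list alone, 2 rose and 1 fell, and the list median was 0.19, at percentile 99.8. Of 18 interferon response genes, Irf1 fell (119 to 52.4 FPKM), at either adjustment, with a median of -0.18 at percentile 33.8.

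Immediate early and heat shock genes, which respond within minutes to handling and stress, were lower as a list in basal cells. Of 19 measured, 6 fell and 7 fell adjusted over the list alone, with none rising. Fosb went from 380.2 to 107 FPKM, the chaperone gene Dnajb1 from 170.04 to 55.4, Fos from 1120.2 to 365, Junb from 266 to 96.0 and the merged locus of Hspa1a and Hspa1b from 268 to 66.1. The median of the list was -0.84, below all random lists. Of 33 p53 and senescence genes, Igfbp5 (6.06 to 1.04 FPKM) and the stress gene Gadd45g (101 to 48.3 FPKM) fell, at either adjustment, with a median of -0.14 at percentile 38.0. Without the immediate early and heat shock list, 180 basal genes remained called, 29 higher and 151 lower. That count only subtracts the 6 called members. It does not show how far a response to handling or stress reaches into genes outside the list.

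In the smaller pathway lists, the Hedgehog co-receptor gene Gas1 fell in basal cells (-1.73 ± 0.43) among 10 measured, at either adjustment, with a median of -0.49 at percentile 1.48. With a minimum of 5 FPKM that median was at percentile 4.05, inside the central range. The hair sheath gene Tchh fell (8.54 to 3.48 FPKM) among 16 hair follicle genes, at either adjustment, with a median of -0.06 at percentile 71.4. None of 19 Notch, 19 sebaceous or 21 cholesterol synthesis genes passed by either adjustment, and their medians were -0.14, 0.21 and 0.11, at percentiles 27.0, 99.6 and 96.5. Among 74 ribosomal protein genes, Rps12 rose (27.4 to 58.8 FPKM) but not adjusted over the list alone, and the median was -0.18, at percentile 1.26.

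Markers of other cell types were few in basal cells. Of 7 fibroblast markers the collagen gene Col5a2 fell (4.62 to 0.695 FPKM). When adjusted over the list alone, 1 rose and 2 fell, with a median of -0.76 at percentile 1.49 (13.5 for the 5 with at least 5 FPKM). Tnni2 was the single muscle marker measured, and it fell from 9.44 to 1.08 FPKM, at either adjustment (median -2.33, percentile 0.855). The 3 melanocyte, 5 Schwann cell, 3 leukocyte, 2 endothelial and 2 adipocyte markers and the single Merkel cell locus (the keratin locus with Krt8) had none passing by either adjustment. Their medians were 0.60, -0.50, 0.07, 0.01, -0.41 and -0.75, at percentiles 96.7, 21.4, 71.0, 72.2, 31.8 and 11.4. No erythroid marker and no mitochondrially encoded gene was tested in basal cells. The sex-linked RNA Xist, in a merged locus, rose from 0.258 to 108 FPKM, and of 4 Y-linked genes none passed by either adjustment, with a median of -0.78 at percentile 0.54. Ddx3y among them had 32.1 and 20.7 FPKM. Xist and the Y-linked genes thus point to a different mix of male and female animals between the genotypes. Sex is to that extent confounded with genotype, and its share in the calls was not tested beyond Igf2 and Peg3.

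Among called loci with a single gene that is not a predicted or RIKEN model, at least 5 FPKM in the higher and at least 0.1 FPKM in the lower group, the largest falls in basal cells were those of the mitochondrial import gene Timm23 (12069.8 to 14.1 FPKM, -9.74 ± 2.40), Igf2 (-6.03 ± 1.49), C1qtnf1 (29.6 to 0.505 FPKM), Clec2d (319.8 to 12.0 FPKM), Cyp2f2 (42.9 to 1.72 FPKM) and Klhl22 (6.69 to 0.418 FPKM). The largest rises under the same limits were those of the splicing factor gene Srrm2 (102 to 2985 FPKM, 4.87 ± 1.20) and the defensin gene Defb6 (20.3 to 151 FPKM), then S100a9, Lzts1 (7.43 to 30.4 FPKM), Chic2 (4.34 to 17.3 FPKM) and S100a8. Outside these limits, the merged Xist locus rose by 8.71, and 2310014L17Rik changed by -8.80, Rusc2 by -6.53 and Rell2 by -4.06, each further than some of the genes listed. The loci of Timm23, Igf2, Srrm2, Top2a and Rps12 contain an annotated short RNA gene. In suprabasal cells Timm23 had 18.4 and 2.58 FPKM, Srrm2 42121 and 46436 FPKM, Clec2d 8.86 and 13.3 FPKM and Klhl22 2.30 and 2.72 FPKM. Igf2 lies on chromosome 7 from 142650766 to 142666816.

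**Figure D1:**
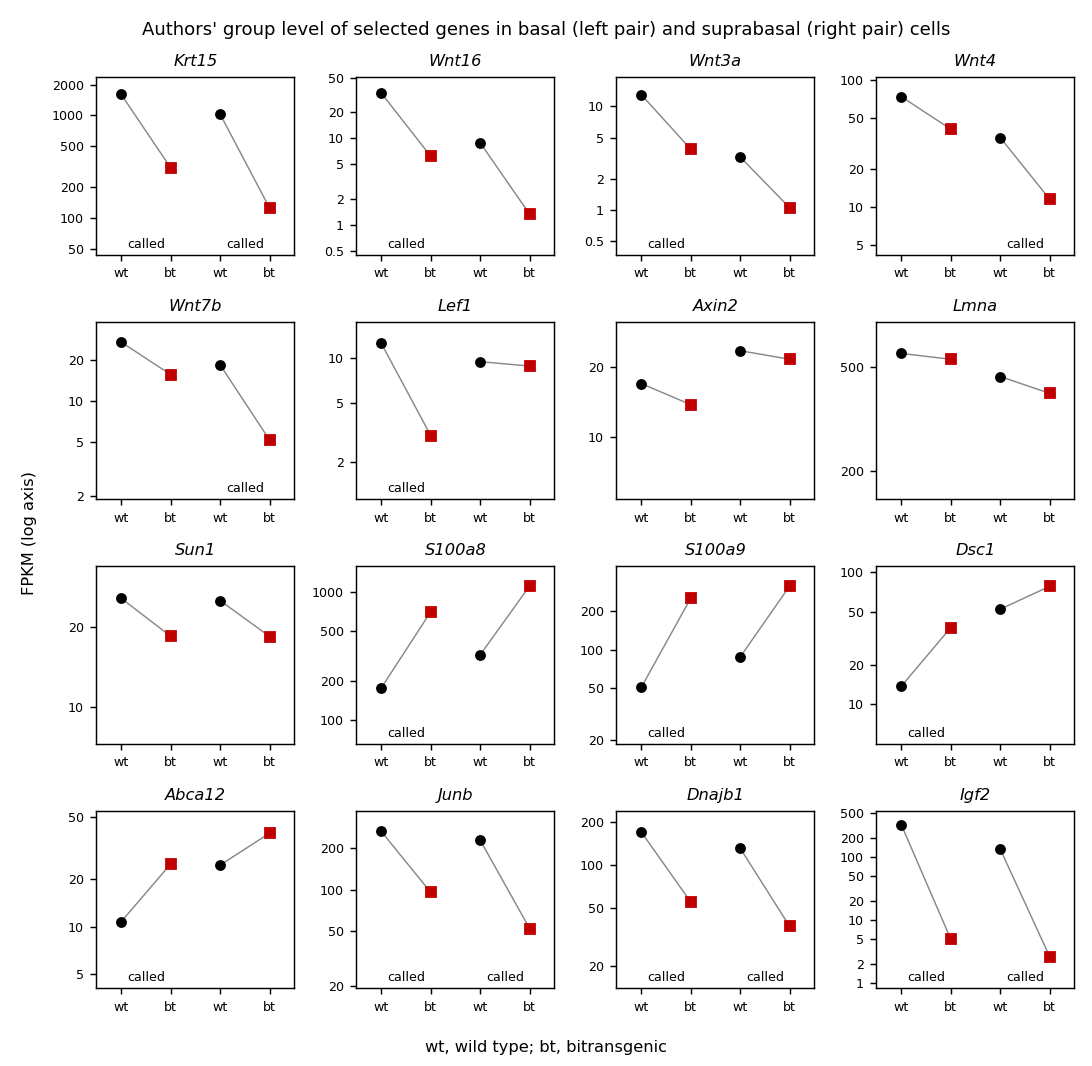
Authors' group level in FPKM (log axis) of 16 genes in wild type (circles) and bitransgenic (squares) cells, basal on the left and suprabasal on the right of each panel; "called" marks q under 0.05. Krt15, Junb, Dnajb1 and Igf2 fell in both layers, and Lmna went from 564 to 536 FPKM in basal cells without being called.

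The authors' p was under 0.05 for 867 of the 11290 basal genes, where 564 are expected by chance, and 701 of the 867 were lower. The median log2 fold change of basal genes with at least 1 FPKM in both groups (expressed genes) was -0.11. After fold changes were centred on the median of expressed genes and readjusted, 41 genes were called, 14 higher and 27 lower. The share lower was then 65.9%, against 82.5% after readjustment without centring and 84.4% at the authors' q. When the authors' p was readjusted over the analysed loci alone, 63 genes were called, 11 higher and 52 lower: of the 47 called genes that the rule names from the tables of single layers 28 remained, and the 19 that ended were Krt15 (readjusted p 0.0941 on the authors' values), Ror1 (0.125), Tmem43 (0.138), Fosb (0.196), Gadd45g, Fa2h, Elovl4, Ccl20, Tnf, Irf1, Lor, Rps12, Cntfr, Cyp2f2, Tnni2, Col4a5, Chic2, Lzts1 and Defb6, while the calls of Celf2, which the rule names for the layer difference, and of Wnt6, Fos, Lrp4, Col5a2, Rell2 and the merged loci of Xist and of 9430008C03Rik, which it does not name, ended too.

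In suprabasal cells, the question was how progerin changes cells that have left the basal layer. Igf2 fell from 135 to 2.64 FPKM, Krt15 from 1025 to 124, Wnt7b from 18.5 to 5.18 and Wnt4 from 35.2 to 11.4. The cornified envelope gene Kprp rose from 3.12 to 16.8 FPKM. The stress-responsive Junb fell from 229 to 52.4 FPKM and Dnajb1 from 131 to 37.4. In all, 54 of 11464 genes were called at the authors' q, 6 higher and 48 lower in bitransgenic cells.

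Among 52 Wnt ligands, receptors and effectors in suprabasal cells, 2 fell and none rose, and 7 fell adjusted over the list alone. Wnt7b changed by -1.84 ± 0.45 and Wnt4 by -1.62 ± 0.40. The 52 genes had a median of -0.24, at percentile 1.67 of the random lists, which again gives no direction of Wnt signalling. Of 20 Wnt targets none passed by either adjustment, and the median was 0.07, at percentile 88.2. Lef1 had 9.48 and 8.86 FPKM (-0.10 ± 0.40), Axin2 23.5 and 21.6 FPKM (-0.12 ± 0.38) and Ctnnb1 184 and 205 FPKM (0.16 ± 0.38), and none passed.

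None of 36 nuclear envelope genes passed in suprabasal cells by either adjustment, and their median was -0.12, at percentile 25.03. Lmna had 460.2 and 397 FPKM, Sun1 25.2 and 18.4, Sun2 24.1 and 20.3, Emd 69.6 and 89.0, Tmpo 37.0 and 37.5, and Lmnb1 25.3 and 20.7 FPKM. Of 36 polarity and spindle genes none passed, while adjusted over the list alone Gnai1, a G protein subunit of the spindle complex, fell (24.6 to 8.82 FPKM), with a list median of -0.15 at percentile 18.7. None of 40 cell cycle genes passed by either adjustment (median 0.02, percentile 89.7).

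The programmes of differentiation had opposite medians in suprabasal cells. Of 34 cornified envelope genes, Kprp alone passed (2.42 ± 0.60). Adjusted over the list alone 7 rose and 1 fell. The late envelope genes Lce1d (13.3 to 61.7 FPKM) and Lce1g (5.54 to 28.5 FPKM) were among the 7, and Cst6 (104 to 45.5 FPKM) was the 1. The list median was 0.63, above all random lists, and 27 of 34 members lay above 0. The Lce1 family is part of the list here too, so these members are not independent. The 24 early differentiation genes had a median of -0.57, below all random lists. Among them the receptor gene Notch3 fell when adjusted over the list alone (23.9 to 10.6 FPKM), but not at the authors' q. Krt1 had 3419 and 1622 FPKM (-1.08 ± 1.62) and Krt10 6574 and 2354 FPKM (-1.48 ± 1.52), and neither passed.

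Wound and stress genes had a median of 0.97 in suprabasal cells (0.62 with a pseudocount of 5 FPKM), above all random lists, although none of 26 passed at the authors' q. Counted as adjusted over the list alone, S100a9 (87.5 to 311 FPKM), S100a8 (324 to 1126 FPKM) and Gjb2 (21.2 to 50.3 FPKM) rose and the growth factor gene Hbegf fell (34.7 to 13.7 FPKM). Of 24 basal keratinocyte genes, Krt15 (-3.04 ± 0.75) and the matrix gene Postn (119 to 38.2 FPKM) fell. Adjusted over the list alone, 1 rose and 3 fell, with a median of -0.27 at percentile 1.67. Itga6 had 106 and 85.1 FPKM, the merged locus of Krt14 and Krt16 1994 and 1534 FPKM, and the merged locus that holds Krt5 and Krt8 5147 and 2591 FPKM, and none passed.

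Immediate early and heat shock genes had the lowest median of the lists with at least 5 measured members in suprabasal cells. Of 19, 5 fell and 10 fell adjusted over the list alone, with none rising. The merged locus of Hspa1a and Hspa1b went from 351 to 59.9 FPKM, and Junb changed by -2.13 ± 0.53. The median of the list was -1.22, below all random lists. Of 34 p53 and senescence genes, Gadd45g fell (68.5 to 16.0 FPKM), and 4 fell adjusted over the list alone, with a median of -0.23 at percentile 5.74. Without the immediate early and heat shock list, 49 suprabasal genes remained called, 6 higher and 43 lower, which again only subtracts the called members.

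Melanocyte markers stood out among the other cell types in suprabasal cells. None of 11 passed at the authors' q, 1 rose adjusted over the list alone (Mlana, 165 to 369 FPKM), and 11 of 11 lay above 0, with a median of 0.86 above all random lists. Of 12 fibroblast markers none passed by either adjustment, with a median of 0.64, above all random lists. The 2 erythroid markers, Hbb-bs (1.21 and 11.5 FPKM) and Hbb-bt (1.38 and 3.94 FPKM), had a median of 1.77, at percentile 99.98, and neither passed by either adjustment. The 6 Schwann cell, 4 leukocyte, 1 endothelial, 2 adipocyte and 1 Merkel cell loci had none passing by either adjustment, with medians of 0.22, 0.17, -0.09, -0.05 and -0.99 at percentiles 92.8, 84.7, 47.2, 56.3 and 7.09. No muscle marker and no mitochondrially encoded gene was tested. The merged Xist locus had 0.236 and 103 FPKM and was not called (8.77 ± 2.94, the authors' q 0.141). Of 4 Y-linked genes none passed and 2 fell adjusted over the list alone, with a median of -0.72 at percentile 1.0.

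Other lists held few called genes in suprabasal cells. The hair sheath gene Tchh fell (8.19 to 2.35 FPKM) among 15 hair follicle genes, at either adjustment, with a median of -0.34 at percentile 3.82. Rps12 rose (22.1 to 139 FPKM) among 74 ribosomal protein genes, at either adjustment, with a median of -0.14 at percentile 7.02. None of 26 barrier lipid, 23 sebaceous, 27 cytokine or 21 cholesterol synthesis genes passed by either adjustment, with medians of 0.05, 0.20, -0.20 and -0.23 at percentiles 88.0, 99.1, 14.3 and 5.96. No gene of the interferon, Notch, Hedgehog, basement membrane or desmosome lists (19, 20, 11, 24 and 31 measured) was called. When adjusted over the list alone, Irf1 fell (78.9 to 27.0 FPKM), as did Notch3, the Hedgehog genes Gas1 and Cdon, and 3 collagen loci with Col4a5, Col4a6 and Col7a1. In the desmosome list Gjb2 rose and the merged locus with Dsg1a fell. The medians of these lists were -0.09, -0.23, -0.02, -0.11 and -0.23, at percentiles 50.7, 10.2, 65.0, 36.0 and 3.56.

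Under the same limits, the largest falls in suprabasal cells were those of Igf2 (-5.67 ± 1.40), the histone gene Hist1h2ak (332 to 9.26 FPKM), the phosphatase gene Ppm1h (61.6 to 2.96 FPKM), the pseudogene Rps2-ps10 (76.7 to 6.32 FPKM), Krt15, and Fras1, which encodes a basement membrane protein (9.76 to 1.19 FPKM). The 4 rises within the limits were those of the BMP signal transducer Smad5 (55.2 to 371 FPKM, 2.75 ± 0.68), Rps12 (2.66 ± 0.65), Kprp and the cytokine receptor gene Cntfr (14.1 to 38.1 FPKM). The other 2 of the 6 called rises were larger: the merged locus of 9430008C03Rik (4.40, 19.8 to 417 FPKM) and Corin (3.80, 0.219 to 3.05 FPKM), whose call ended when the authors' p was readjusted over the analysed loci. The loci of Igf2, Hist1h2ak, Ppm1h, Smad5 and Rps12 contain an annotated short RNA gene. In basal cells Hist1h2ak had 293 and 235 FPKM, Rps2-ps10 6.44 and 9.43 FPKM and Smad5 53.6 and 82.2 FPKM.

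The authors' p was under 0.05 for 815 of the 11464 suprabasal genes, where 573 are expected by chance, and 592 of the 815 were lower. The median log2 fold change of suprabasal genes with at least 1 FPKM in both groups was -0.08. No gene had a q under 0.01, because the smallest p in the table carries a q of 0.0161.

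**Figure D2:**
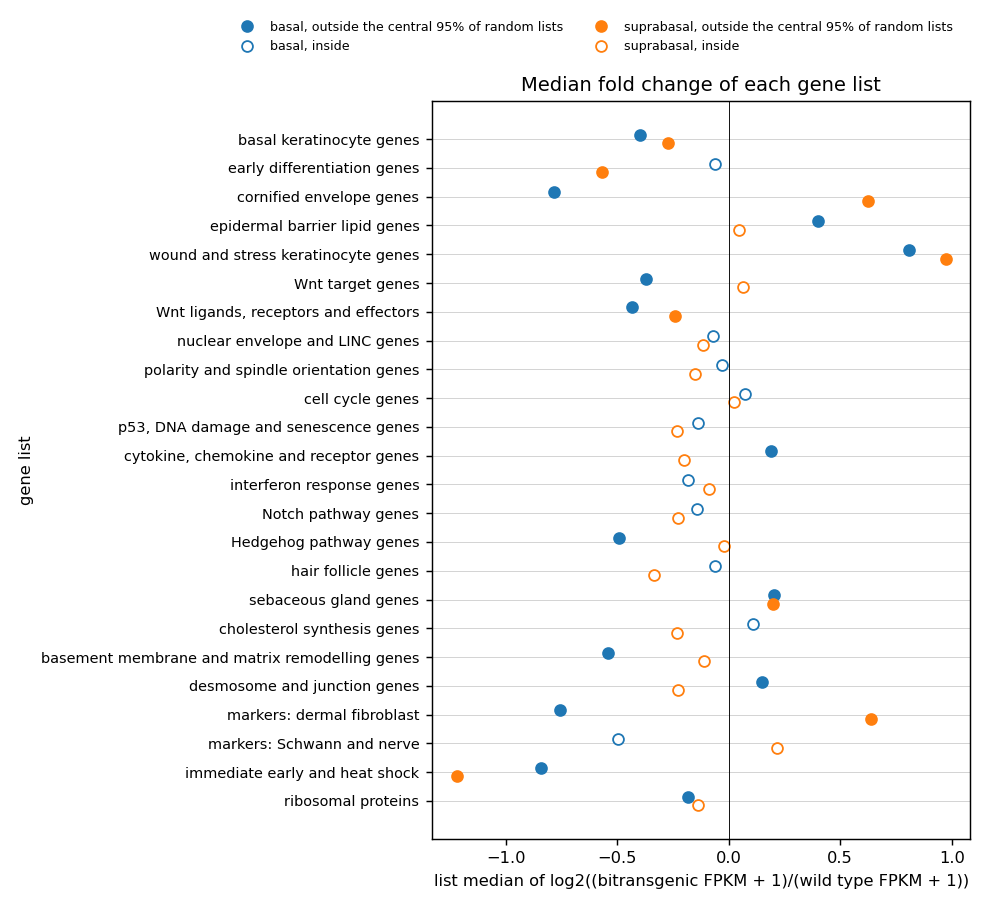
Median log2((bitransgenic FPKM + 1)/(wild type FPKM + 1)) of each gene list with at least 5 measured members in each layer, with filled points outside the central 95% of random lists. Cornified envelope genes lay at -0.78 in basal and 0.63 in suprabasal cells, and immediate early and heat shock genes at -0.84 and -1.22.

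Comparing the layers asks which changes were shared and which depended on the layer. Of 10583 genes tested in both, 26 were called in the same direction: Igf2, Krt15, Junb, Dnajb1, Gadd45g, Tchh, Fras1 and 17 others fell, and Rps12 and Cntfr rose. With the authors' p readjusted over the analysed loci in each layer, 14 of these 26 remained, 14 lower and none higher. The shared falls included Id1 (111 to 48.7 FPKM in basal and 109 to 28.3 FPKM in suprabasal cells) and Id3, a pair of BMP targets, and the cytokine signal inhibitor Socs3 (117 to 48.5 and 74.6 to 22.1 FPKM). The LDL receptor-related gene Lrp4 fell by 0.93 on the log2 scale in basal and by 1.83 in suprabasal cells, and the imprinted gene Peg3 from 23.9 to 10.3 and from 15.9 to 5.29 FPKM. Wnt6, Fos, Col5a2, Xist, Rell2, Corin, Gnai1, Lce1d, Lce1g, Notch3, Hbegf, Mlana, the haemoglobin genes, Id1, Id3, Socs3, Lrp4 and Peg3, and the other genes outside the rule for named genes, were chosen after their values were seen.

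Of 154 genes lower in basal cells and 47 lower in suprabasal cells, 24 were lower in both, where 0.684 would be expected if calls were independent (two-sided Fisher's exact test, p = 1.54e-32). Of 29 and 5 higher, 2 were higher in both, where 0.0137 would be expected (two-sided Fisher's exact test, p = 7.21e-05). No gene was higher in basal and lower in suprabasal cells, and 1 merged locus (9430008C03Rik, Gm23925 and Gm26003) was lower in basal and higher in suprabasal cells. Of the genes called in basal cells, 86.9% had the same direction in suprabasal cells, beside 60.5% of all genes. Across genes, which are not independent replicates, the fold changes of the layers had a Pearson r of 0.268 and a Spearman rho of 0.255. The layers share title stems, and genes are not independent, so the exact tests describe the tables.

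Few genes had a fold change that differed between the layers by test. The p of this Wald test was under 0.05 for 326 of 10583 loci, where 529 are expected by chance. The test is therefore conservative on these data, and the small count does not show that the layers responded alike. Cst6 was 1 of 4 called: its log2 fold change was 1.69 in basal and -1.19 in suprabasal cells, a difference of -2.89 ± 0.59 (Wald test on the authors' values, adjusted p 0.00477). Celf2, an RNA-binding protein gene, went from 9.16 to 1.43 FPKM in basal and from 14.1 to 31.3 FPKM in suprabasal cells (difference 3.84 ± 0.89, adjusted p 0.0417 on the authors' values). Rusc2 differed by 7.64 ± 1.73 (adjusted p 0.0355 on the authors' values), with a basal bitransgenic level of 0.0426 FPKM. The merged locus of 9430008C03Rik differed by 6.35 (adjusted p 0.0017 on the authors' values). The loci of Celf2 and 9430008C03Rik contain an annotated short RNA gene. Next in order were Clec2d (5.33, adjusted p 0.0857 on the authors' values), Kprp (4.85), Rps2-ps10 (-4.15), Hist1h2ak (-4.85) and Srrm2 (-4.73), which did not pass. Of 181 genes called in 1 layer alone, 3 differed between layers by the test. With the SE taken from the authors' test statistic, 5 loci were called, and the merged locus of 9430008C03Rik was the 1 shared with the 4.

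**Figure D3:**
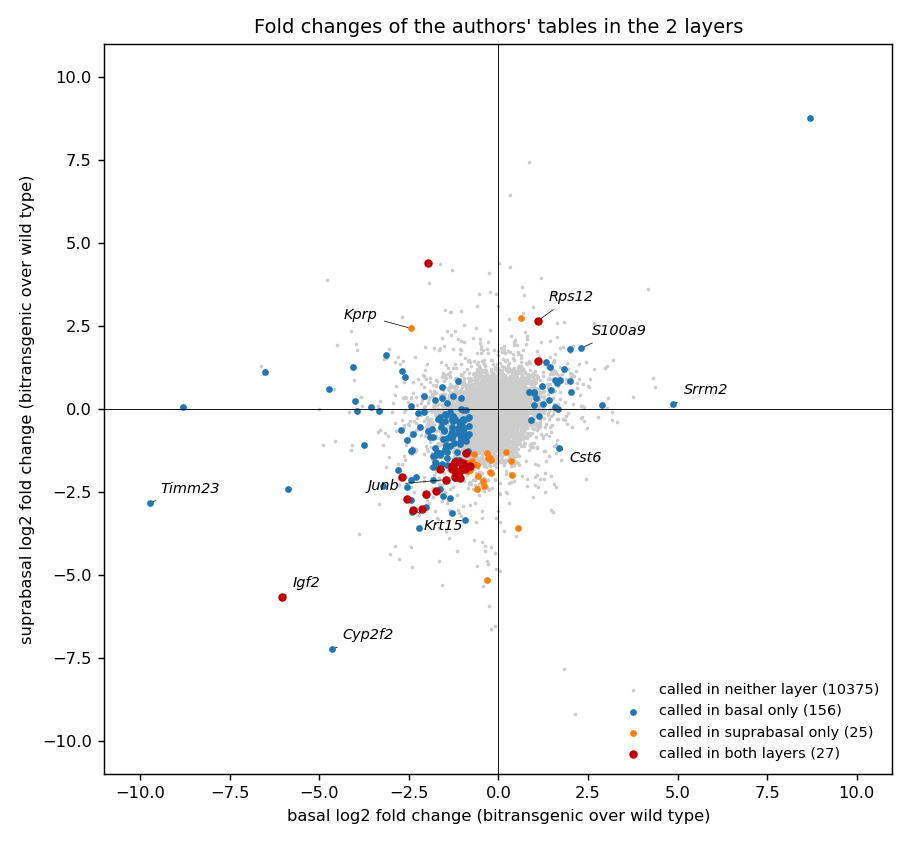
Log2 fold change (bitransgenic over wild type) in basal cells on the horizontal and in suprabasal cells on the vertical axis, for 10583 genes tested in both layers, coloured by where they were called. Igf2 lies at -6.03 and -5.67, Krt15 at -2.38 and -3.04, and Cst6 at 1.69 and -1.19.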

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

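The tests of misestimated levels and of short RNA genes were chosen only after the large changes had been seen, and the test of each gene's difference between layers was chosen before.

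A difference between the layers in the response to genotype singled out 4 loci. For Cst6 the suprabasal minus the basal log2 fold change was -2.89. For Rusc2 it was 7.64, and for Celf2 it was 3.84. For the merged locus of 9430008C03Rik, Gm23925 and Gm26003 it was 6.35.

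Levels that no comparison used were found for 26 loci of the basal and 26 loci of the suprabasal table with the status HIDATA. These loci are listed at 0 in wild type cells. The 26 loci together hold 18.4% of the summed bitransgenic level in basal and 10.8% in suprabasal cells, and 23 of the 26 in each layer lie on the mitochondrial chromosome. The merged locus of Gm26917 and Gm26924, which lies on chromosome 17, had the highest level of the 26, with 22478 FPKM in basal and 19758 FPKM in suprabasal bitransgenic cells. In bitransgenic basal cells mt-Nd1 stood at 18691 FPKM and mt-Cytb at 12479.6 FPKM. In bitransgenic suprabasal cells mt-Nd1 stood at 17978 FPKM and mt-Cytb at 10806.5 FPKM. The listed 0 gives no fold change, and it does not show that these RNAs were absent in wild type cells.

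Several of the largest changes, such as those of Timm23, Srrm2 and Rusc2 in basal cells, were far smaller or opposite in suprabasal cells. Of 28 called changes of at least 3 log2 units, 23 were measured in the other layer, and 30.4% of these 23 showed at least 50% of the change there in the same direction, against 59.1% of 186 called changes from 1 to 3 units. These 28 changes lie in 27 loci, since Igf2 is counted in both layers, and 12 of the 27 overlap an annotated short RNA gene, where the median of length-matched random sets is 6, which puts them at percentile 99.5. These values are in line with a misestimated level in 1 group, and with reads of short RNA genes inside some loci, though Igf2 and Krt15 fell in both layers and selection for size alone would also lower the share. A biological difference between the layers stays open and could account for some of these genes, since the 4 groups have no replicate values with which to test it.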

How the results depend on the processing

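The alternatives of readjusting over the analysed loci, leaving out loci with short RNA genes, leaving out immediate early and heat shock genes, readjusting for the shared count and taking the SE from the test statistic were chosen only after the data had been seen.

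Of 28 alternatives for the counts of genes, 18 stayed within 1.5 times the count reported and 10 did not. The 186 basal calls became 44 at a q under 0.01, 63 after readjustment with a minimum of 1 FPKM, over both tables together or over the analysed loci, 75 with a minimum of 5 FPKM, 61 without merged loci, and 41 after centring. Fewer were called because readjusted values replaced the authors' q, which could not be recomputed, or because the q threshold was stricter. Centring includes such a readjustment, which alone gave 63, and the cause of the further fall to 41 was not tested. At a q under 0.01, 0 suprabasal genes and 0 shared genes were called, since the smallest p carries a larger q. The suprabasal count was otherwise between 37 and 54, the shared count was 14 after readjustment over the analysed loci and otherwise between 22 and 26, and the layer difference between 3 and 5. Of the 6 suprabasal rises, 2 remained beside 41 falls without loci that overlap a short RNA gene. Without merged loci and readjusted, 3 rises and 37 falls remained. The minimum of 1 FPKM removed no gene and so tests nothing. Leaving out the immediate early and heat shock list only subtracts its called members, so its counts were fixed in advance.

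Of 140 alternative medians of the lists read first, 135 stayed on their side of the random lists. Centring and the setting without a minimum could not change a side. Centring shifts a list and its random lists alike, and no locus lay under the minimum of 1 FPKM. Each of these settings holds 60 medians among these and the other lists, and they test nothing. Against unmatched random lists, the Wnt target median in basal cells (-0.37) was at percentile 3.97 and that of basal keratinocyte genes in suprabasal cells (-0.27) at 5.27, both inside the central range, while the cell cycle median in basal cells (0.073) was outside at 98.7. Without merged loci the suprabasal median of basal keratinocyte genes was -0.24, at 2.99. With a minimum of 5 FPKM the polarity median in suprabasal cells was -0.25, outside at 2.32. The cause was not tested. Of 275 other list medians 269 stayed on their side. Of 180 named fold changes 177 stayed within their SE and no called one changed sign; the 3 others (Igfbp5, C1qtnf1 and Klhl22 in basal cells) moved with a pseudocount. Of genes not called, Lmna (-0.07 to 0.04), Sun2 (to 0.11) and Ctnnb1 (-0.08 to 0.03) changed sign in basal cells after centring, within their SE. Centring subtracts the layer's median (-0.11 in basal and -0.08 in suprabasal cells) from every fold change. That is less than the SE of each named gene, so centring could move none of them beyond it.

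Leaving out a replicate and blocking by title were not run, because only pooled group values were analysed here. The depth of the samples is unknown, so how far it limits the small levels is not known.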

Other observations

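The histone and insulin-like growth factor groups, the list differences between layers and most tests were chosen only after the values had been seen; the test of the remaining imprinted genes was chosen before its result.

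Histone genes were lower as a group in bitransgenic cells of both layers. Of 73 histone loci in basal cells 64 lay below 0, with a median log2 ratio of -0.40, and of 72 in suprabasal cells 60 lay below 0, with a median of -1.07. Both medians lay below all 10000 random lists. At the authors' q, 3 fell and none rose in each layer. In suprabasal cells Hist1h4h fell from 112 to 21.2 FPKM and H2afj from 90.2 to 18.1 FPKM, and in basal cells Hist1h4a fell from 394 to 205 FPKM and H1f0 from 135 to 72.7 FPKM. Hist1h2bn fell in basal cells (401 to 182 FPKM) and had 272 and 490.5 FPKM in suprabasal cells, where it was not called. With the authors' p readjusted over the analysed loci, the basal calls of Hist1h4a, H1f0 and Hist1h2bn ended. The cell cycle list did not fall beside them (medians 0.07 in basal and 0.02 in suprabasal cells). The short RNA genes Rpph1 (3027 to 1458 FPKM), Rnu12 (1843 to 540 FPKM) and Scarna2 (229 to 96.6 FPKM) were also called lower in basal cells. None of them was called in suprabasal cells, and the basal calls of Rpph1 and Rnu12 ended on readjustment. The cause of the histone falls was not tested.

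Beside Igf2, Igfbp3 and Igfbp5, some called genes of the same pathway were picked after their values were seen, so no change of the pathway was tested. In basal cells the receptor substrate gene Irs1 fell from 14.9 to 6.13 FPKM, the kinase subunit gene Pik3r1 from 24.6 to 10.2 FPKM, and the transcription factor gene Foxo1 from 15.1 to 6.30 FPKM. In suprabasal cells Irs1 had 12.3 and 6.60 FPKM, Pik3r1 19.2 and 14.9 FPKM and Foxo1 15.8 and 13.6 FPKM, and none was called. The BMP ligand gene Bmp2 fell in suprabasal cells by 2.02 on the log2 scale, from 9.70 FPKM in wild type. This call ended on readjustment (readjusted p 0.0541 on the authors' values). In basal cells, where Id1 and Id3 fell too, Bmp2 had 20.1 and 13.6 FPKM and was not called. A link between Bmp2 and the falls of Id1 and Id3 was not tested.

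The suprabasal minus basal change was also read per list, for 26 lists, of which 9 lay outside the central 95% of random lists. If genes and lists were independent, 1.3 would be expected. They are not, since genes in a list vary together and lists share members such as Gjb2, so the excess over 1.3 is not a test. Cornified envelope genes had a median difference of 1.22, with 13 above 0 and 11 below, and early differentiation genes of -0.51, with 3 above 0 and 21 below. Barrier lipid genes had -0.44, sebaceous genes -0.36, cytokine genes -0.34, desmosome genes -0.34 and wound and stress genes -0.29. Basement membrane genes had 0.34 and fibroblast markers 0.70.

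Immediate early and heat shock genes, read as 1 list, were lower in bitransgenic cells of both layers. Scaling of whole libraries is argued against, because the list median minus that of all expressed genes was -0.74 in basal and -1.15 in suprabasal cells. A difference in tissue handling between the animals of each genotype could lower both programmes. The highest of the 4 medians, heat shock genes in suprabasal cells, was -0.34, between the bounds set for it and inside the range of random lists (percentile 6.99), although 2 of the 6 heat shock loci fell there at the authors' q, as they did adjusted over the list alone; the suprabasal median of immediate early genes was -1.38, and the basal medians were -0.84 for immediate early and -1.01 for heat shock genes. Handling and an effect of progerin cannot be told apart, because the labels analysed here give 1 protocol without saying when or in what order the animals were handled, and each group has 1 pooled value.

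Igf2 and Peg3, a pair of imprinted growth genes, were lower in bitransgenic cells of both layers, Plagl1 was called lower in suprabasal cells alone (37.1 to 14.6 FPKM, readjusted p 0.0541 on the authors' values), and the merged locus of H19 and Mir675 had 5771 and 711 FPKM in basal and 2869.8 and 137 FPKM in suprabasal cells without being called. RNA from dermal fibroblasts in wild type samples is argued against in suprabasal cells. There the 12 measured of 20 markers had a median of 0.64, with 9 above 0 and 3 below. Vim (316 and 492 FPKM) is 1 of the 12 but is also a melanocyte gene, and melanocyte markers had a median of 0.86 there. The collagen gene Col1a1 had only 3.02 and 4.20 FPKM. In basal cells the explanation stays open despite the sort for keratinocytes. The 7 markers measured there had a median of -0.76 (percentile 13.5 for the 5 with at least 5 FPKM). Thy1 (28.7 and 51.9 FPKM) and Vim (2.32 and 6.24 FPKM) were the 2 above 0, and neither has to come from fibroblasts. Dcn is also on the imprinted list. A different mix of male and female animals is argued against for Igf2, which differed from the median of the Y-linked genes by -4.88 in suprabasal cells (combined SE 1.51) and -5.13 in basal cells (combined SE 1.81), but not for Peg3 (-0.30 in basal cells, combined SE 1.07). The imprinted list, written after Igf2 and Peg3 were seen, had a median of -0.57 in basal cells (21 measured, 2 lower at the authors' q and 4 adjusted over the list alone, percentile 0.19) and -0.10 in suprabasal cells (23 measured, 3 and 4 lower, percentile 39.6), while the members neither called nor already looked at lay at percentiles 52.6 and 74.3, which decides nothing, because the called genes were left out. Genes picked because they were called and an effect of progerin therefore cannot be told apart and stay open, the effect of progerin untested.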
